A study of Mus musculus with 6 samples.

How the data were processed

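Gene counts were analysed for 6 RNA-seq libraries of mouse (C57/B6) fetal liver cells: 3 taken at day 0 and 3 after 30 h of culture with erythropoietin, the last 6 h with DMSO. Groups and replicate numbers come from the labels. The deposited files hold whole-number counts per gene, 1 file per library, made by the authors. The submitters' processing notes name cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2, and genome build mm10, without their settings. RNA was total RNA purified with a column kit, per the labels' protocols. Whether counting used strand is not given in the sources used here, so reads of overlapping genes on opposite strands may not be separated. Reads shared by near-identical genes, such as the paired globins, may have been dropped or split in counting.

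Each file lists 54232 gene IDs, of which 54165 were found in GENCODE M21, an annotation of the same assembly as mm10, and 67 were not; 29342 had a count in any library. Symbols, positions and gene types come from that annotation. Library totals ranged from 19241780 to 29949173 counts. Counts in the IDs not found made up at most 0.0047% of a library. All 37 mitochondrial genome genes had 0 counts, so the list of mitochondrially encoded proteins, with 13 genes, could not be tested.

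Genes were kept by edgeR's filterByExpr at its defaults, which left 16150. Library scaling used TMM, with factors of 1.18, 1.18 and 1.19 at day 0 and 0.84, 0.87 and 0.82 at 30 h. The main test was edgeR's quasi-likelihood F test with robust fitting on the deposited counts (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 changes, kept with the results, were derived from the F statistic. The biological coefficient of variation was 14.2% over both groups, 5.28% within day 0 and 20.5% within 30 h, so the 30 h libraries set the precision. The steps were tested on simulated data: of 15709 simulated genes tested, 63, 66 and 65 were changed by 1.5-fold, 2-fold and 4-fold, and 22.2%, 65.2% and 90.8% of them were called, with 3 unchanged genes called. The simulation changed 200 genes, raised and lowered about equally, with the same spread in both groups. It therefore did not test scaling, recovery or false calls where most genes change and the 30 h spread is larger.

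The 38 gene lists (30 of biology and 8 of cell type markers) were fixed before the data were examined, and 37 could be tested. Each was tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Of these lists 20 passed, 15 higher and 5 lower, and 0 remained past 0.05 when the correlation was estimated from the libraries (7 at an unadjusted p below 0.05). Named genes follow a rule fixed at the same time: the 8 largest rises and 8 largest falls past the threshold with a mean of at least 10 CPM, non-overlapping groups and an established symbol; 22 genes of erythroid, chromatin and apoptosis biology; and, in each list, the largest rise and fall, the most abundant member and the one with the smallest adjusted p. Hba-x, Hbb-bh1 and the members of lists added later were named after their values were seen. Some items that the rule names are not reported here.

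Shares of counts and genes detected after thinning were compared by two-sided exact permutation tests (scipy 1.17.1), where 3 against 3 cannot give a p under 0.1. Alternatives were other scalings (DESeq2 size factors, totals only, upper quartile, globin genes left out), other filters, DESeq2 1.42.0, limma-trend, a test against a 1.5-fold change, the replicate number as a block, each library left out, and, chosen after seeing the data, removal of each library's GC trend. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 4.30 and 94.9, so none was counted as a copy of another. The value was 11.7 between 30 h replicates 1 and 2, but 94.9 and 52.1 between each of them and 30 h replicate 3. By this measure on raw counts replicate 3 stood apart. Correlations of log2 CPM at 30 h were 0.987 for replicates 1 and 2, 0.984 for 2 and 3, and 0.979 for 1 and 3. On that scale replicates 1 and 3 differed most.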

Results

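Messenger RNA was measured in mouse E13.5 fetal liver cells depleted of cells carrying Ter-119, a surface antigen of maturing red cells. The series concerns how chromatin and the nucleus condense while erythroblasts mature. It holds 3 libraries of the purified cells at day 0 and 3 libraries of cells kept for 30 h in medium with erythropoietin, the hormone that drives red cell production. The 30 h cells received the solvent DMSO at 24 h, for 6 h, as the control for the caspase inhibitor Z-VAD-FMK, whose libraries were not analysed here. Library totals were 29949173, 29278777 and 27754279 counts at day 0, and 24154481, 19241780 and 19391388 counts at 30 h. The single comparison, 30 h against day 0, asks which transcripts changed during this culture. Levels below are TMM-scaled CPM (each count relative to the scaled library total), as mean ± SD with n = 3 in each group, and adjusted p-values for single genes come from the edgeR quasi-likelihood test.

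Most of the measured transcriptome differed between the groups. Of 16150 genes tested, 5553 were higher and 6483 lower at 30 h, together 74.5%. The level changed by at least 2-fold in 3324 of the higher and 4561 of the lower genes, and by at least 8-fold in 450 and 1471. Protein-coding genes split into 4608 higher and 6267 lower of 14363, whereas long non-coding genes split into 488 higher and 151 lower of 856, and pseudogenes into 353 higher and 47 lower of 754. The values of the groups did not overlap for 79.7% of genes, where chance alone gives 10%. Higher genes were 46.1% of the calls with TMM and 29.1% when libraries were scaled by their totals only, a setting that moved the median log2 change of all genes from -0.09 to -0.58. Nothing in the labels says that the libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these samples.

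The globin list had the largest median rise of the lists tested, 6.19 on the log2 scale. Hbb-bs, an adult beta globin gene (chromosome 7, 103826534 to 103828096, mm10), went from 370 ± 44.1 to 79735 ± 23294 CPM (edgeR adjusted p = 6.9093e-07). Hba-a1, an adult alpha globin gene, rose 73.2-fold, from 128 ± 4.54 to 9394 ± 1001 CPM. Of the 9 globin genes measured, 7 rose and 2 fell. The genes that fell were the embryonic globins Hbb-y, 9.20-fold lower at 30 h, and Hba-x, while Hbb-bh1, the other embryonic beta-type gene, rose 91.7-fold. Reads of the near-identical pairs Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, and Hbq1a and Hbq1b cannot be assigned with certainty, so the split within each pair is uncertain. Limma's camera test placed the globin list above other genes (adjusted p = 0.003254), with adjusted p = 0.5116 with an estimated correlation.

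Heme synthesis and transport genes rose in 12 of 14 cases, and 1 fell (13 and 1 adjusted over the list alone). Alas2, the erythroid enzyme of the first step of heme synthesis, rose 102-fold, from 17.5 ± 1.75 to 1791 ± 157 CPM (edgeR adjusted p = 2.3521e-07), and Cpox, a later enzyme of the pathway, rose 7.28-fold. Flvcr1, which encodes a heme exporter, was 2.11-fold lower. The camera adjusted p of the list was 1.999e-06, and adjusted p = 0.2272 with an estimated correlation. Red cell membrane and skeleton genes rose in 18 of 19 cases, among them Slc4a1, encoding the anion exchanger band 3 (64.5-fold, from 76.5 ± 1.90 to 4937 ± 1774 CPM). In 30 h replicates 1, 2 and 3 Slc4a1 stood at 6602, 5137 and 3071 CPM. Aqp1, encoding a water channel, was the member that fell, by 2.12 on the log2 scale. This list had a camera adjusted p of 3.303e-07, and adjusted p = 0.4961 with an estimated correlation. Counts adjusted over the list alone equalled those over all genes here and in 32 of the 37 lists tested, and the lists where they differed are named with both counts.

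**Figure D1:**
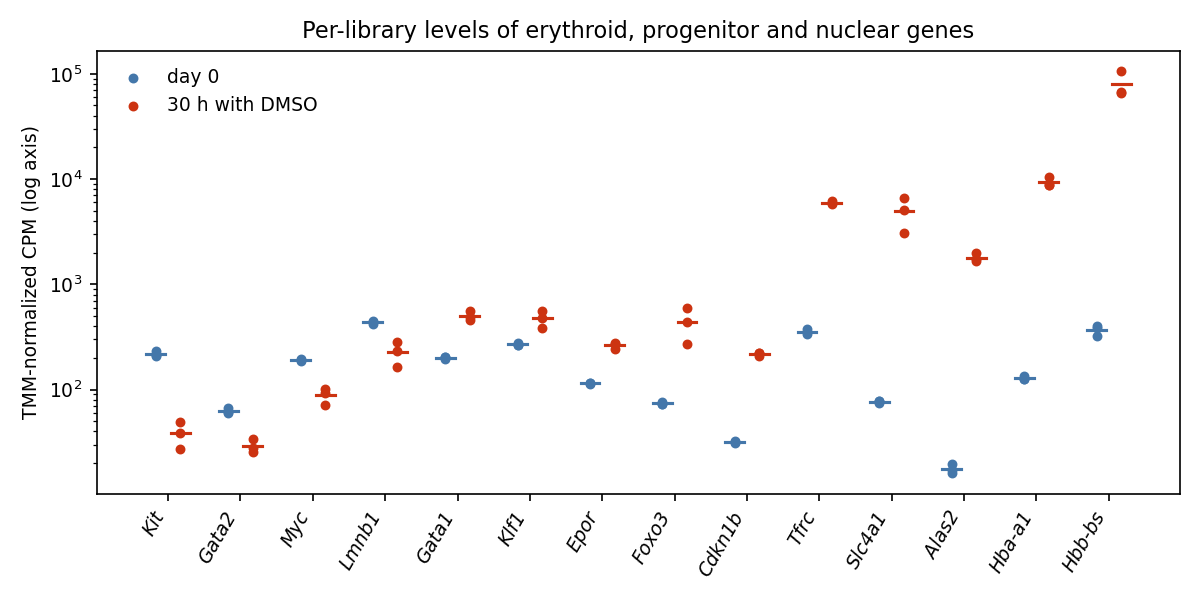
TMM-scaled CPM of 14 erythroid, progenitor and nuclear genes in each library, on a log axis; points are single libraries and bars are means of 3. Alas2 went from 17.5 to 1791 CPM and Kit from 218 to 38.4 CPM, and no gene drawn had overlapping groups.

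The 9 globin genes held 0.121% ± 0.00930 (SD, n = 3) of all counts at day 0 and 10.4% ± 2.44 (SD, n = 3) at 30 h. In 30 h replicates 1, 2 and 3 the share was 8.73%, 9.28% and 13.2%. The 100 most abundant genes of each library held 15.8% ± 0.0770 at day 0 and 28.5% ± 3.41 at 30 h (SD, n = 3 each), a difference of 12.6 percentage points that was 4.77 with globin and mitochondrial genes left out (15.8% ± 0.0765 and 20.6% ± 1.69). After thinning every library to 19241780 counts, 22771 ± 16.3 genes were detected at day 0 and 21463 ± 364 at 30 h (SD, n = 3 each). Each of these differences separated all 3 libraries of one group from all 3 of the other, with p = 0.1 in the two-sided exact permutation test, the smallest p that 3 against 3 can give. The 37 genes of the mitochondrial genome had 0 counts in all 6 libraries, and Icam4, a membrane gene, also had 0, so neither entered a test.

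Of 13 erythroid transcription factors, 8 were higher and 2 lower (9 and 2 adjusted over the list alone), against 6 and 3 with scaling by totals only, where the median log2 change went from 0.82 to 0.33, and 12 and 1 with the GC trend removed, that is, the dependence of each library's counts on GC content. Gata1, the central erythroid factor, rose 2.52-fold (edgeR adjusted p = 1.4816e-05), Foxo3 rose 5.91-fold and E2f2, a regulator of the cell cycle, 9.53-fold. Klf1, an activator of beta globin, rose 1.76-fold, but with scaling by totals only its log2 change of 0.82 became 0.33, no longer past the threshold. Bcl11a, a repressor of embryonic globins, was 1.76-fold lower. The camera adjusted p was 0.01208, and adjusted p = 0.6526 with an estimated correlation. Among genes of erythropoietin signalling, 8 rose and 6 fell of 14, with the feedback inhibitor Cish 41.0-fold higher, the kinase gene Pim1 12.5-fold higher, Epor, the receptor, 2.29-fold higher and Stat5a 3.35-fold lower (camera adjusted p = 0.1282, but 0.03881 with scaling by totals only and 0.0193 with the GC trend removed). Iron genes did not move as a list relative to other genes (6 higher and 5 lower of 13, camera adjusted p = 0.4106), although Tfrc, the transferrin receptor, rose from 356 ± 19.8 to 5955 ± 185 CPM and Aco1, which encodes an iron regulatory protein, was 3.27-fold lower. The fry test, which compares a list with no other genes, called the iron list (fry adjusted p = 0.0009541). It called 33 of the 37 lists tested, so a fry call does not set a list apart. The iron counts were 3 higher and 6 lower with scaling by totals only, 3 and 5 with upper-quartile scaling, and 3 and 4 without day 0 replicate 2.

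Stem and progenitor genes went down, with 13 of 18 lower and 2 higher. Kit, the receptor of stem cell factor, fell from 218 ± 12.6 to 38.4 ± 10.9 CPM (edgeR adjusted p = 1.8082e-05), Gata2 from 62.7 ± 4.24 to 29.2 ± 4.37 CPM and Myc from 190 ± 4.98 to 88.2 ± 15.4 CPM. The members called higher were Fli1, at 1.37-fold, and Lyl1, at 1.24-fold. Under scaling by totals only their log2 changes were -0.04 and -0.18, neither past the threshold (adjusted p = 0.7562 and 0.1465 in edgeR). The call of Lyl1 was also lost with upper-quartile scaling, no filter on low counts and the replicate number as a block (adjusted p = 0.09972, 0.1691 and 0.05657 in edgeR), and without day 0 replicate 1, 2 or 3 or 30 h replicate 2 (adjusted p = 0.1119, 0.08778, 0.06422 and 0.06533 in edgeR). The list's camera adjusted p was 0.00308, and adjusted p = 0.4961 with an estimated correlation. Markers of hepatoblasts, endothelium and mesenchyme fell in the same libraries.

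Cell cycle genes and cell cycle inhibitors rose in the same libraries. Of 20 mitosis genes, 15 rose and none fell, including Mki67, a marker of cycling cells (10.3-fold), and Top2a, encoding a DNA topoisomerase (1.90-fold). DNA replication genes rose in 12 of 20 cases and none fell, with Rrm2, a subunit of ribonucleotide reductase, going from 307 ± 4.93 to 1534 ± 127 CPM (edgeR adjusted p = 1.1065e-06). Inhibitors of the cycle rose in 11 of 12 cases, including Cdkn1b (6.86-fold), Cdkn1a (9.85-fold) and the stress gene Gadd45a (25.1-fold). Cdkn1c was the exception, 11.9-fold lower at 30 h. Camera adjusted p-values were 8.742e-05 for mitosis, 0.004738 for replication and 5.865e-05 for the inhibitors, and with an estimated correlation they were adjusted p = 0.5706, adjusted p = 0.5116 and adjusted p = 0.1096. With scaling by totals only, the log2 change of Top2a was 0.44 and no longer past the threshold, and the replication list had 9 genes higher and 5 lower. For that list the counts were 11 and 3 with upper-quartile scaling, 12 and 3 without 30 h replicate 1 or with no filter on low counts, and 15 and 2 without 30 h replicate 3.

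Condensins, the complexes that compact chromosomes, rose in 7 of 8 subunits. Smc4 went from 161 ± 12.2 to 765 ± 113 CPM (edgeR adjusted p = 4.3177e-06) and Smc2 rose 3.47-fold. The list had a camera adjusted p of 0.00308, and adjusted p = 0.5116 with an estimated correlation. In the list of cohesin, its regulators and Ctcf, 5 of 11 rose, led by Wapl, which releases cohesin from DNA (2.96-fold), and Rad21 (1.92-fold), none fell, and the camera adjusted p was 0.05225. That value was 0.02932 with DESeq2 size factors, 0.04152 with upper-quartile scaling, 0.0197 with no filter on low counts and 0.04602 with the replicate number as a block, but 0.6953 with the GC trend removed (6 genes higher and 1 lower) and adjusted p = 0.6526 with an estimated correlation. Without 30 h replicate 3 it was 0.003195 and 9 rose, and with scaling by totals only 4 genes were higher and 2 lower. Ctcf, the boundary-binding factor, did not pass the test (171 ± 5.66 and 205 ± 45.7 CPM, edgeR adjusted p = 0.1759), but it did without 30 h replicate 3 (log2 change 0.43, adjusted p = 0.000182) and with the GC trend removed (0.37, adjusted p = 0.03822).

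Other chromatin and nuclear lists went both ways. Linker and variant histones gave 7 higher and 3 lower of 15, with H3f3a 4.13-fold higher and H2afy2, a macroH2A gene, 10.3-fold lower (camera adjusted p = 0.278), and 5 higher and 5 lower with scaling by totals only. H3f3a went from 14.3 to 59.2 CPM. H3f3b, the most abundant member, went from 452 to 632 CPM, a 1.40-fold rise, but its log2 change was -0.011 with scaling by totals only. Among deacetylases, repressive methyltransferases and heterochromatin proteins, 9 rose and 6 fell of 21, with Kmt5c 2.72-fold higher, and Hdac2 1.44-fold and the corepressor gene Trim28 3.83-fold lower (camera adjusted p = 0.3879), and with scaling by totals only 4 were higher and 12 lower. Kmt5a, the methyltransferase of histone H4, rose 1.30-fold with TMM but had a log2 change of -0.11 when scaled by totals only, and with no filter on low counts it did not pass (adjusted p = 0.05785). DNA methylation genes gave 4 higher and 5 lower of 12, with Tet2 6.02-fold higher and the de novo methyltransferase Dnmt3b 8.67-fold lower (camera adjusted p = 0.9468); their median log2 change of -0.07 was 0.43 with the GC trend removed and 0.21 without 30 h replicate 3. At the nuclear envelope 9 rose and 3 fell of 15. Lmna, encoding lamin A, rose 2.35-fold, Lmnb1 was 1.94-fold lower and Lmnb2 2.82-fold lower (camera adjusted p = 0.09691, but 0.02164 without 30 h replicate 3 and 0.02184 with the GC trend removed), and with scaling by totals only 4 were higher and 4 lower. Nuclear pore and transport genes were lower in 14 of 20 cases and higher in 3, with Xpo5 4.24-fold lower and Tpr 1.95-fold higher (camera adjusted p = 0.09691, but 0.0255 without 30 h replicate 1, 0.0423 with upper-quartile scaling, 0.008286 with no filter on low counts and 0.01201 with the GC trend removed). Of these, 0 were higher and 15 lower with scaling by totals only, and without 30 h replicate 3 the counts were 5 and 14. The log2 change of Tpr was 0.48 and no longer past the threshold when scaled by totals only (adjusted p = 0.1227). Xpo7, an exportin, did not pass (92.1 ± 2.10 and 102 ± 27.5 CPM, edgeR adjusted p = 0.4671), but did without 30 h replicate 3 (log2 change 0.34, adjusted p = 0.004957).

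The caspase list also holds activators, inhibitors and nuclease partners of caspases. It did not move relative to other genes, with 5 higher and 4 lower of 18 (camera adjusted p = 0.3879). The fry test called this list (fry adjusted p = 0.01025), as it did 33 of the 37 lists tested. The counts were 4 higher and 8 lower with scaling by totals only, 9 and 4 without 30 h replicate 3, and 8 and 3 with the GC trend removed. Parp1, encoding a DNA damage sensor, was 3.22-fold lower (edgeR adjusted p = 0.00013601), and Casp1, an inflammatory caspase gene, was 3.43-fold higher. The BCL2 family gave 9 higher and 5 lower of 15, with Bnip3 20.7-fold higher, the survival gene Bcl2l1 2.27-fold higher and Bok 4.79-fold lower (camera adjusted p = 0.1536, but 0.02325 with the GC trend removed). Genes tied to enucleation were lower in 10 of 18 cases and higher in 1, Diaph3, a formin gene, at 3.30-fold (camera adjusted p = 0.1652, but 0.02803 with no filter on low counts). For that list the counts were 2 higher and 4 lower with the GC trend removed, where its median log2 change went from -0.39 to -0.06, 1 higher and 16 lower with scaling by totals only, and 4 higher and 12 lower without 30 h replicate 3. The medians of the caspase, iron, histone, nuclear envelope and repressive chromatin lists were above 0 with TMM and below 0 when scaled by totals only, the last also with upper-quartile scaling and with no filter on low counts.

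Autophagy, ubiquitin system, p53 target and antioxidant genes rose as lists. Of 20 autophagy genes, 15 rose and 3 fell, with Atg4d 4.57-fold and Gabarap 3.18-fold higher (camera adjusted p = 0.0004416, and adjusted p = 0.1096 with an estimated correlation). Ubiquitin system genes of late erythroblasts rose in 11 of 12 cases, led by Trim10 at 22.5-fold (camera adjusted p = 0.0003106, and adjusted p = 0.4961 with an estimated correlation). Targets of p53 rose in 10 of 13 cases and fell in none (camera adjusted p = 0.000357, and adjusted p = 0.1096 with an estimated correlation). Antioxidant genes rose in 13 of 17 and fell in none, with the heme-degradation enzyme gene Blvrb 13.0-fold and Gpx1 5.11-fold higher (camera adjusted p = 1.753e-05, and adjusted p = 0.1277 with an estimated correlation). Immediate early and heat shock genes gave 9 higher and 2 lower of 15, with Atf3 21.7-fold higher and the chaperone gene Hsph1 2.25-fold lower (camera adjusted p = 0.09691, but 0.007798 with the GC trend removed). With scaling by totals only the counts of higher and lower genes were 10 and 5 for autophagy, 7 and 0 for the ubiquitin system, 10 and 2 for p53 targets (10 and 1 with upper-quartile scaling), 13 and 3 for antioxidant genes and 7 and 6 for immediate early and heat shock genes (8 and 4 with upper-quartile scaling).

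Metabolic lists differed in direction. Glycolysis genes rose in 14 of 18 cases and fell in 1, with Slc2a1, the glucose transporter, at 8.78-fold and Aldoa at 3.61-fold (camera adjusted p = 0.0009177, and adjusted p = 0.5066 with an estimated correlation). Cholesterol genes rose in 11 of 16 and fell in 3, with Insig1 3.34-fold higher and Dhcr7 2.39-fold lower (camera adjusted p = 0.01855, and adjusted p = 0.5706 with an estimated correlation). Glycolysis counts were 8 higher and 3 lower and cholesterol counts 7 and 4 with scaling by totals only. RNA polymerase I and ribosome biogenesis genes were lower in 15 of 16 cases (16 adjusted over the list alone) and higher in none. Polr1b, a polymerase I subunit, fell from 173 ± 4.94 to 26.1 ± 6.81 CPM (edgeR adjusted p = 8.9026e-06) and Ncl, nucleolin, was 1.99-fold lower. That list's camera adjusted p was 0.0001519, and adjusted p = 0.4961 with an estimated correlation.

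All 14 interferon response genes rose. Isg15, a ubiquitin-like protein gene (chromosome 4, 156199424 to 156200818, mm10), went from 2.56 ± 0.129 to 942 ± 200 CPM (edgeR adjusted p = 2.5459e-07), and Rsad2, an antiviral gene, rose 71.4-fold. The median log2 change of the list was 3.54, with a camera adjusted p of 2.6e-07, and adjusted p = 0.1096 with an estimated correlation. In the same libraries macrophage markers went both ways, with Ctss 9.93-fold and Lyz2 5.34-fold higher and Vcam1 29.1-fold and Cd5l 62.9-fold lower.

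**Figure D2:**
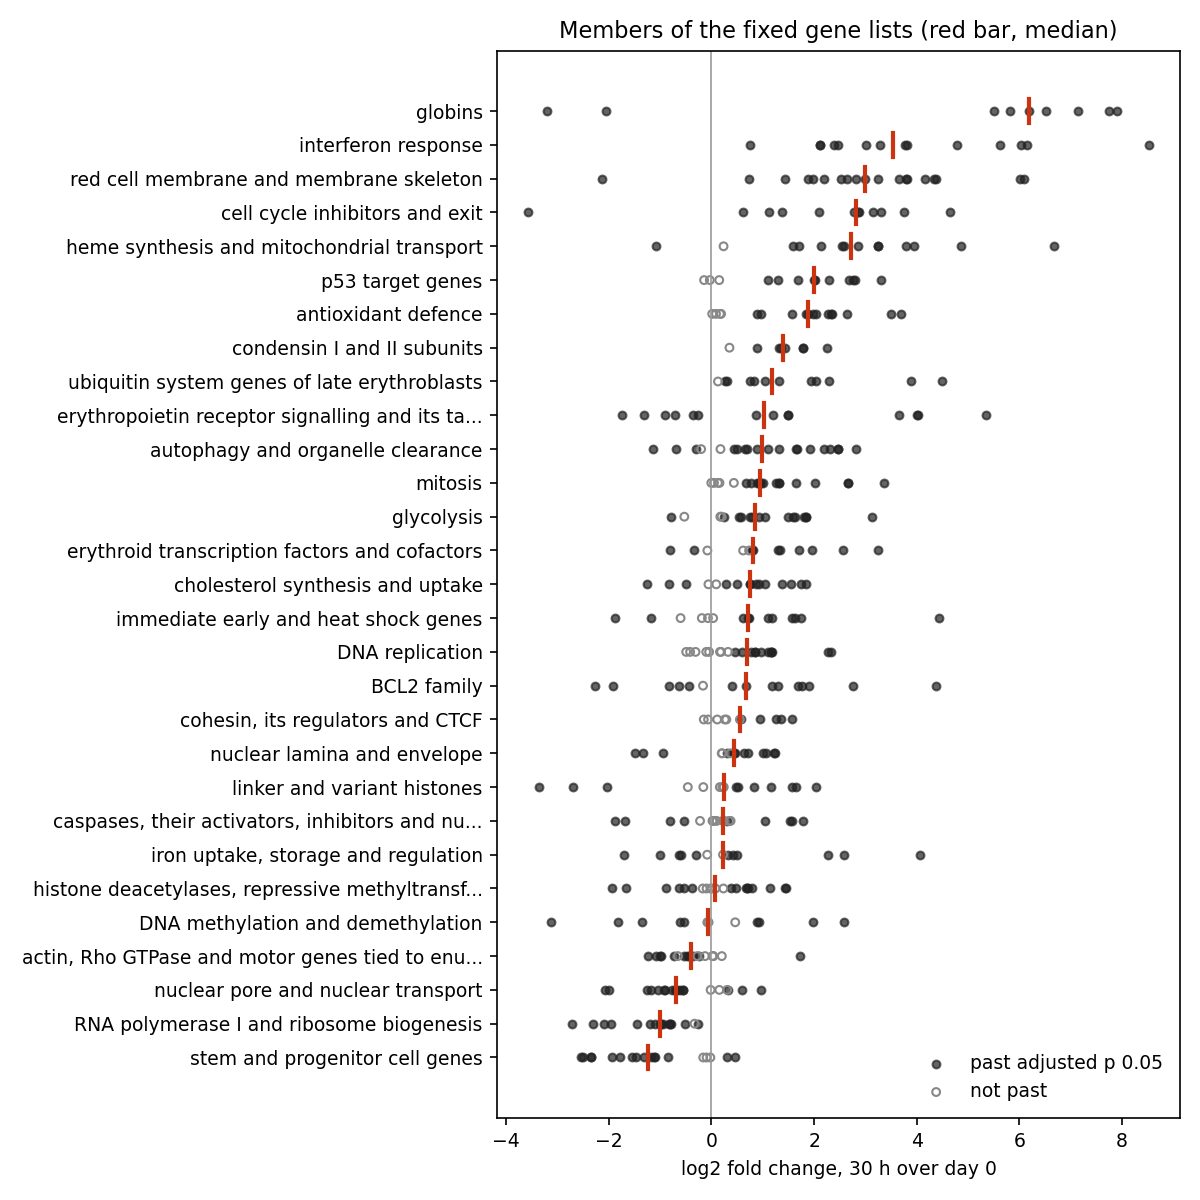
Log2 fold change, 30 h over day 0, of each tested member of 29 gene lists; filled points passed the edgeR test, open points did not, and red bars are list medians. The globin list has the highest median, 6.19, and the stem and progenitor list the lowest, -1.24; with scaling by totals only, the caspase, iron, histone, nuclear envelope and repressive chromatin medians fell below 0.

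Markers of non-blood cells of the fetal liver fell. Endothelial markers were lower in 9 of 9 cases, mesenchymal markers in 9 of 10 (10 adjusted over the list alone) and hepatoblast markers in 12 of 14, with median log2 changes of -4.76, -5.77 and -4.03. Afp, the fetal serum protein of hepatoblasts, fell from 7067 ± 226 to 1336 ± 658 CPM (edgeR adjusted p = 0.0005939), and Col1a1, a collagen gene of mesenchyme, from 700 ± 97.7 to 8.85 ± 3.68 CPM. Camera adjusted p-values were 0.0003106 for endothelial, 0.0003653 for mesenchymal and 0.0002929 for hepatoblast markers, and with an estimated correlation they were adjusted p = 0.1096, adjusted p = 0.5066 and adjusted p = 0.5706.

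Markers of other blood cells were mixed, and none of these lists passed the camera test with TMM. The fry test, which called 33 of the 37 lists tested, called the granulocyte, megakaryocyte and mast cell lists (fry adjusted p = 0.03184 each). It also called the B lymphoid list (0.002417), but not the macrophage list (0.1191). Macrophage markers gave 7 higher and 4 lower of 14 (7 and 5 adjusted over the list alone), with Lyz2 higher but Vcam1 29.1-fold lower. Their median log2 change was 0.52, their mean -0.06, and the camera adjusted p 0.3251. The macrophage median was 0.03 with scaling by totals only (6 higher and 6 lower), 0.07 at 5 CPM or more and 0.94 with the GC trend removed (9 and 3). Granulocyte markers gave 5 higher and 3 lower of 12, with S100a9 6.30-fold higher and Mpo, myeloperoxidase, 3.50-fold lower (camera adjusted p = 0.3211). Megakaryocyte markers gave 1 higher, Pf4, and 6 lower of 12 (camera adjusted p = 0.247), but 4 higher and 4 lower with the GC trend removed, where their median log2 change went from -0.31 to 0.13. Mast cell markers gave 2 higher and 3 lower of 7 (camera adjusted p = 0.8048, median log2 change -0.46, but 0.16 with the GC trend removed and 0.04 without 30 h replicate 1), and B lymphoid markers 0 higher and 4 lower of 8, with Ebf1 10.3-fold lower (camera adjusted p = 0.247). When scaled by totals only, 7 B lymphoid markers were lower and granulocyte markers gave 4 higher and 6 lower, with a median of -0.32 against 0.17. With the GC trend removed the granulocyte counts were 8 and 2, the median was 0.71 and the list passed (camera adjusted p = 0.0406).

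**Figure D3:**
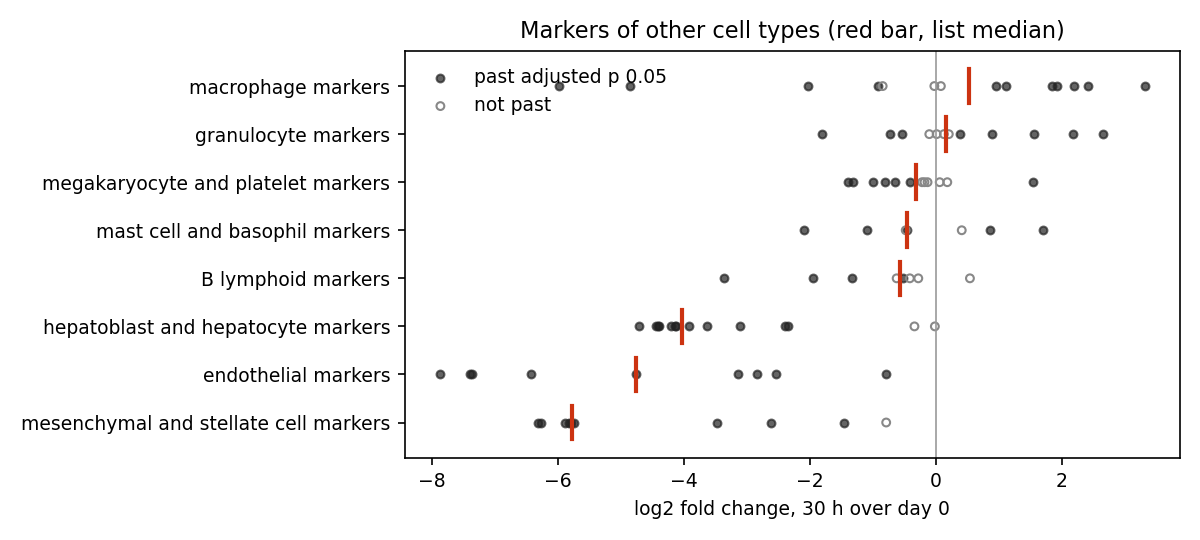
Log2 fold change, 30 h over day 0, of markers of 8 other cell types; filled points passed the edgeR test, open points did not, and red bars are medians. Mesenchymal, endothelial and hepatoblast medians lie at -5.77, -4.76 and -4.03, and the other medians between -0.57 and 0.52; the granulocyte median falls below 0 with scaling by totals only, and the megakaryocyte and mast cell medians rise above 0 with the GC trend removed.

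The genes with the largest rises among those at 10 CPM or more were Isg15, Tph1, Hbq1b, Gpnmb, Hbb-bs, AW011738, Trib3 and Hbb-bt. Tph1, the enzyme of peripheral serotonin synthesis, went from 0.212 ± 0.0661 to 69.7 ± 11.6 CPM, Gpnmb, a lysosomal membrane glycoprotein gene, from 0.890 ± 0.168 to 204 ± 69.1 CPM, and Trib3, a stress-induced pseudokinase gene, from 3.76 ± 0.433 to 574 ± 39.0 CPM (edgeR adjusted p = 3.631e-07, 1.2459e-06 and 2.3521e-07). AW011738, a neighbour of Isg15 on chromosome 4, rose 154-fold. The largest falls were in Stab2, Lyve1, Cdh5, Col14a1, Tril, Rgn, Megf6 and Gulo. Stab2, Lyve1 and Cdh5 are endothelial genes, and Rgn and Gulo encode enzymes of hepatocytes. Stab2 had 2405 counts over the day 0 libraries and 5 over the 30 h libraries, a ratio of 247 after scaling with an exact 95% counting interval of 105.8 to 762, and Cdh5 had 3609 and 11, a ratio of 169 with an interval of 94.1 to 338. Gulo fell from 99.2 ± 10.9 to 1.20 ± 0.581 CPM (edgeR adjusted p = 1.4293e-06). These intervals cover counting error only.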

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

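Removal of the GC trend was chosen after seeing the data; all other settings were fixed before. Scaling by totals only gave 3601 genes higher at 30 h, 1957 of them by at least 2-fold, against 5553 and 3324, and kept 10084 of the 12036 calls in their direction, with 18 opposite. It turned Kmt5a (-0.11), Fli1 (-0.036), Lyl1 (-0.18) and H3f3b (-0.011), none of them past the threshold there; this setting lowers the log2 change of all genes. At least 5 CPM in 3 libraries left 2157 genes higher and 2673 lower by at least 2-fold, with 11257 genes tested instead of 16150. An estimated correlation left 0 of 20 lists and fry, which compares a list with no other genes, called 33; outside these 2 settings 0 calls of lists were lost, except that the globin list could not be tested with its genes left out, and 17 were gained, 5 by cohesin. Over the fits leaving out 1 library, higher genes ranged from 5041 to 6233, lower genes from 5976 to 7008, those higher by at least 2-fold from 3321 to 3734, those lower by at least 2-fold from 4481 to 4875 and lists from 20 to 22. The differences in globin share ranged from 8.89 to 11.1 percentage points, in the top 100 share from 10.7 to 13.7 (4.77 with globin and mitochondrial genes left out, 9.64 for the top 10), and in genes detected from -1426 to -1107 (-1005 with globin counts left out, -1251 for genes with at least 5 counts). With the GC trend removed, 54.8% of calls were higher and 70 calls were opposite. DESeq2's Wald test kept 11821 calls and limma-trend 11916. The replicate number as a block gave 11531 calls, 11455 of them shared, and 5254 higher. Same-numbered libraries correlated at -0.105, 0.105 and -0.0293 and others at -0.108 to 0.141. No pairing by number was seen, but so few libraries cannot exclude it. Leaving out mitochondrial genes moved nothing, since they had 0 counts. Of 131 named genes, 112 kept their side of the threshold and direction in all settings. In a simulation with 200 changed genes a 1.5-fold change was often missed, which need not hold where most genes change. Depth was not varied.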

Other observations

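The gene lists of this paragraph and the next, and the tests after them, were chosen after the results were seen. Camera p-values of these lists come from the same data, so they are no independent evidence. Of 22 integrated stress response genes, 16 were higher and 2 lower at 30 h, with Ddit3, a stress transcription factor, 70.6-fold, Chac1 39.9-fold, Nupr1 28.7-fold and Atf4 itself 7.93-fold higher, while Psat1 and Phgdh, enzymes of serine synthesis, were 1.72-fold and 1.52-fold lower (edgeR, camera adjusted p = 2.202e-05, and adjusted p = 0.4156 with an estimated correlation). Cytosolic ribosomal protein genes rose in 69 of 76 cases and fell in 3, whereas ribosome biogenesis genes fell in 15 of 16. Nuclear-encoded respiratory chain genes rose in 68 of 80 and fell in 2, and proteasome genes rose in 28 of 38 and fell in 3. Their camera adjusted p-values were 6.564e-11, 9.478e-11 and 7.577e-05, each with adjusted p = 0.55 with an estimated correlation, and all 3 medians stayed above 0 under every scaling. With scaling by totals only the counts were 56 higher and 5 lower for ribosomal proteins, 52 and 7 for the respiratory chain and 15 and 9 for the proteasome. Cytosolic tRNA synthetases gave 5 higher and 4 lower of 18 (4 and 4 adjusted over the list alone; camera adjusted p = 0.891), and 3 higher and 11 lower when scaled by totals only, 10 and 5 without 30 h replicate 3, 8 and 4 with the GC trend removed, and 3 and 3 without day 0 replicate 1 or 3 or 30 h replicate 2 and 3 and 4 without day 0 replicate 2.

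Nuclear non-coding RNAs also differed, with 5 higher and 3 lower of 10 (5 and 5 with scaling by totals only). Neat1, the scaffold of paraspeckles, went from 3.52 ± 0.654 to 360 ± 53.1 CPM and Malat1, a nuclear speckle RNA, from 11.7 ± 1.62 to 124 ± 8.46 CPM, while Meg3 was 5.58-fold lower (camera adjusted p = 0.1996). Core histone genes gave 9 higher and 1 lower of 20 tested (9 and 1 became 6 and 1 adjusted over the list alone, camera adjusted p = 0.09429). The list held 46 genes, and the others were not kept by the count filter. These became 5 and 2 with scaling by totals only, 6 and 2 with upper-quartile scaling, and 14 and 1 of 24 without 30 h replicate 1, and at 5 CPM or more 2 could be tested, both higher. Cardiac muscle genes, present at day 0 with Myl2 at 52.4 ± 6.03 CPM, were lower in 12 of 14 cases and higher in none (camera adjusted p = 0.000451, and adjusted p = 0.55 with an estimated correlation).

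Markers of hepatoblasts, endothelium and mesenchyme fell together. If other blood cells did not change in culture, dilution of all non-erythroid RNA by erythroid RNA would lower their markers alike. But the medians of the 33 non-blood and 53 blood cell markers were -4.14 and -0.18, a difference of -3.96 (permutation over genes, p = 2e-05, the smallest these permutations can give). This p treats genes as independent, but hepatoblast markers had an estimated correlation of 0.953, so it overstates the evidence. The blood cell markers went both ways, with an SD of 1.70, so changes in those cells that offset dilution stay open. Loss of hepatoblasts, endothelium and mesenchyme in culture is a candidate explanation that was not tested, and culture time, medium and DMSO are confounded.

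Interferon response genes rose while cells were in culture. A larger share of RNA from macrophages like those at day 0 would raise macrophage markers by about as much, but their median lay 3.02 below (value -3.02, permutation over genes, p = 0.00026, SD of the 14 markers 2.72), with Lyz2 and Ctss higher and Vcam1 and Cd5l lower. That p also treats genes as independent, whereas macrophage markers had an estimated correlation of 0.656, so it overstates the evidence. RNA of macrophages or monocytes of another kind, or changed in culture, stays open. The GC trend, a Spearman correlation of -0.208 between log2 change and GC content over 14363 protein-coding genes, left a median of 3.82 once removed. An interferon response of the cells themselves, or of a minority of them, may remain and was not tested.

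DNA replication and mitosis genes rose together with Cdkn1b, Cdkn1a and Gadd45a. Removing the GC trend left the median of these 40 genes 0.88 above that of all genes, against 0.96 before. Of the 40, 27 were called higher and 0 lower by edgeR, with log2 changes from -0.49 to 3.37 and an I-squared of 96.4%. Of the 20 replication genes, 5 were lower with scaling by totals only. Loss of non-cycling cells cannot be told apart from a change within cycling cells, because the levels of these genes in the lost cells are unknown.

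The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 5553 genes higher and 6483 lower, and the highest other split 0 and 0 by edgeR, with at most 43 genes at an unadjusted p below 0.05 and 0 by limma-trend; in each case 1 split, the real one itself, gave as many. For lists the real split gave 20 and the highest other 22, and 6 splits, the real one among them, gave at least as many. The other splits mix 2 libraries of one group with 1 of the other, so the group difference adds to the spread within each side. Their 0 gene calls were therefore to be expected and do not show whether the real grouping could arise by chance. For lists, these splits carry part of the real difference, and a preset correlation does not account for it.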
